A study of Mus musculus with 4 samples.

How the data were processed

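Uterine RNA of intact 6-week-old female mice of 2 Hdac3 genotypes, f/f and d/d, was measured on Affymetrix expression arrays, with 2 arrays per genotype. Per the labels' protocols, total RNA was extracted from uterine tissue with an RNeasy kit, and biotinylated cRNA was prepared by the Affymetrix procedure. The deposited values are intensities made by RMA (robust multi-array average, which corrects background, normalizes between arrays and summarises the probes of a probe set), per the submitters' processing notes. The software that ran RMA and its version are not given in the sources used here. RMA output is usually on a log2 scale, whereas the deposited intensity values ran from 2.03 to 10374.5 and were taken to be linear. Array medians were 7.78 and 7.76 for f/f replicates 2 and 3, and 7.79 and 7.92 for d/d replicates 4 and 5. The log2 of each value was taken before any test, and no further normalization was applied.

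The table held 45037 probe sets, none of them Affymetrix control probe sets. In the platform annotation, 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none listed. Of the single-gene probe sets, 34741 matched a current symbol by gene ID in the RefSeq gene table of mouse assembly GRCm38.p6, and 204 kept the platform's symbol. Because no genome build is named for the deposited values, no coordinates are given, and that table was used for names and neighbours only. For a gene with several probe sets, the probe set with the highest mean log2 value over all 4 arrays was used, which gave 18193 genes. Probe sets with several symbols or none were left out of the gene-level test. No detection calls came with the values and no dim probe sets were removed. The lower quartile of all gene-level log2 values was 2.45, and a mean near or below it lies at the floor of the arrays, where background compresses differences.

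Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes at default settings, two-sided) with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences are d/d minus f/f on the log2 scale, SE is limma's moderated standard error, and folds are the brighter over the dimmer genotype. The eBayes prior had 3.20 degrees of freedom and an SD of 0.13. A set of 40 gene lists (565 members, 515 of them measured) covering uterine hormone responses, pathways and markers of cell types that uterine tissue or its surroundings could hold was fixed before the data were examined. The lists were tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 40 lists. Beside this, camera with the correlation estimated from the 4 arrays was run, as was fry. Fry tests whether the genes of a list move, on balance, one way, and in its mixed form whether they change in either direction. Neither form compares a list with other genes. Members of a list were also adjusted over the list alone.

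Named genes followed a rule set before the data were examined. In each direction it took the 12 genes with the largest absolute log2 difference among those past the threshold. It also required both d/d arrays on the same side of both f/f arrays, and a brighter genotype at or above the median of all gene-level values (4.58). Genes without a defined name were passed over. Hdac3 and up to 4 members of each list, by largest absolute difference, were added. Genes named outside this rule are said to be so.

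The procedure was tested on simulated arrays of 18193 genes with 2 arrays per group. It called 0% of 50 genes changed 1.5-fold, 50% of 50 changed 2-fold, 96% of 50 changed 4-fold and 100% of 50 changed 8-fold. Beside these 123 changed genes it also called 9 unchanged ones. The number of arrays limits the precision. The labels number the arrays but do not say that each came from its own animal, so p-values measure the spread between these samples, which may be technical. Arrays of 1 genotype did not hold the same values, with identical entries on 400 probe sets for the f/f pair and 392 for the d/d pair. No hybridisation date, estrous stage or litter is given in the sources used here, so batches could not be examined.

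Alternatives set before the data were examined were a further quantile normalization, centring each array on its median, keeping only genes at or above the median level, eBayes with trend and robust settings, the mean of all probe sets of a gene, the probe set level, a minimum fold of 1.5 with and without the adjusted p, and leaving out each array in turn. For the lists, they also included the estimated correlation and fry. Setting log2 values under 4 to 4 was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.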

Results

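Transcript levels were measured in whole uteri of 6-week-old female mice described as intact, with no treatment recorded. Hdac3 encodes a histone deacetylase that works as the catalytic subunit of the NCoR/SMRT corepressor complexes. In the usual notation of mouse genetics, f/f marks an allele flanked by loxP sites and d/d the same allele after deletion. The labels give 2 arrays for Hdac3 f/f (replicates 2 and 3) and 2 for Hdac3 d/d (replicates 4 and 5), and the series title ties the gene to pregnancy. The single comparison of the design is therefore which uterine transcripts differ when Hdac3 is deleted. Over all genes, Pearson's r of log2 values was 0.991 between the f/f arrays and 0.994 between the d/d arrays, and it lay between 0.984 and 0.988 across genotypes. Genes are not independent replicates, so these values only describe the arrays.

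Hdac3 itself was read by 1 probe set. Its log2 value was 7.42 and 7.28 on the f/f arrays and 7.65 and 7.73 on the arrays labelled Hdac3 d/d. The difference of 0.34 (SE 0.11) ran opposite to the label and had an adjusted p of 0.288 in limma. Where this probe set lies relative to the deleted part of the gene is not given in the sources used here, and a probe set outside that part checks nothing. The group is therefore called the arrays labelled d/d, and every direction below rests on labels that Hdac3 transcript did not verify.

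Between genotypes, 47 of 18193 genes passed the threshold, 17 higher and 30 lower in the arrays labelled d/d. The most prominent losses were of the fat cell transcripts Fabp4 and Adipoq and of the anion transporter Slc26a7, each more than 30-fold. The largest gains were of Guca2b (uroguanylin, a peptide activator of guanylate cyclase C), A2ml1 (a protease inhibitor of the alpha-2-macroglobulin family) and Sprr2d (a small proline-rich protein of epithelia). In camera at its preset correlation, the cholesterol synthesis, epithelium, interferon and cell cycle lists passed as higher and the adipocyte and progesterone response lists as lower, each with adjusted p = 0.564 with an estimated correlation. Of the epithelium, interferon and cell cycle members, limma passed 0 over all genes, with 10, 12 and 3 at an unadjusted p under 0.05.

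Among the 12 named genes that rose, Guca2b went from a log2 mean of 2.74 ± 0.16 (SD, n = 2) to 6.71 ± 0.41 (SD, n = 2), 15.7-fold (SE of the log2 difference 0.22, limma adjusted p = 0.024). A2ml1 rose by 3.21 on the log2 scale (SE 0.12, adjusted p = 0.0198) and Sprr2d by 3.19 (SE 0.26, adjusted p = 0.0381). Sprr2f, a related gene induced by estrogen in uterine epithelium, rose from 9.80 ± 0.26 to 11.61 ± 0.10 (SD, n = 2 each), and probe sets for this family may not separate its near-identical members. Akr1c18, the 20-alpha-hydroxysteroid dehydrogenase that inactivates progesterone, rose by 2.44 (SE 0.15), with close relatives in the same gene cluster. Slc26a4 (pendrin, an anion exchanger) rose by 2.42 (SE 0.14). The matrix genes Fbn2 (fibrillin-2) and Col8a1 (a chain of collagen VIII) rose by 1.97 (SE 0.12) and 1.41 (SE 0.12). Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 1.47 (SE 0.14). Cyp51, the sterol 14-alpha-demethylase, rose by 1.49 (SE 0.12), Ager (the receptor for advanced glycation end products) by 1.61 (SE 0.11) and Rgs4 (a regulator of G protein signalling) by 1.59 (SE 0.10).

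The named genes that fell included 3 adipocyte transcripts. Fabp4, a fatty acid binding protein, went from 8.81 ± 0.47 to 3.03 ± 1.13 (SD, n = 2 each), 54.7-fold, and Adipoq (adiponectin) from 7.79 ± 0.56 to 2.37 ± 0.89, 42.9-fold. Retn (resistin) fell by 3.04 on the log2 scale (SE 0.22). Slc26a7 went from 8.08 ± 0.79 to 2.99 ± 0.09 (SD, n = 2 each), 33.9-fold (SE of the log2 difference 0.36, limma adjusted p = 0.0278). Fst, which encodes the activin antagonist follistatin, went from 5.02 to 2.13, and Crabp2, a retinoic acid binding protein, from 5.93 to 2.96. Cyp2e1, a cytochrome P450, fell by 3.00 (SE 0.25) and Ripor2 by 2.78 (SE 0.18). Tex15, a gene of germ cell development, fell by 2.70 (SE 0.16), Mndal, one of a cluster of similar interferon-inducible genes, by 2.54 (SE 0.25), Vit (vitrin, a matrix protein) by 2.36 (SE 0.15) and Atp8a1 (a phospholipid flippase) by 2.26 (SE 0.15). Group means of Cyp2e1 (1.84), Fst (2.13) and Adipoq (2.37) in the arrays labelled d/d lay below the lower quartile of all genes (2.45), at the floor of the arrays. Close above it lay the f/f means of Slc26a4 (2.52), Guca2b (2.74), Akr1c18 (2.90) and A2ml1 (2.96), and, in the arrays labelled d/d, the means of Crabp2 (2.96), Slc26a7 (2.99), Tex15 (3.00) and Fabp4 (3.03). The folds of all these genes, risen or fallen, depend on background.

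**Figure D1:**
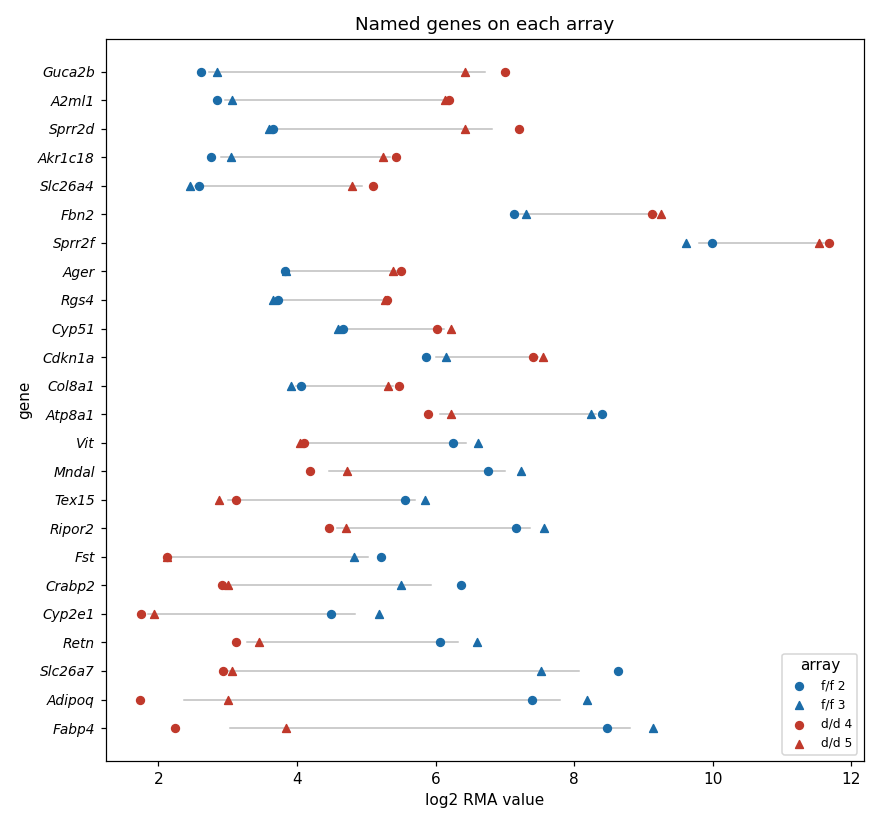
Log2 RMA value (horizontal axis) of the 24 named genes (vertical axis) on each of the 4 arrays; points are single arrays, blue for f/f and red for arrays labelled d/d, and grey lines join the genotype means. In every gene shown, both arrays labelled d/d lie on the same side of both f/f arrays, from Guca2b (3.97 higher) to Fabp4 (-5.77).

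Adjusted p-values of the 47 genes ran from 0.0198 to 0.0477 in limma, and all 47 had both arrays labelled d/d on the same side of both f/f arrays. Over all genes, 8174 (44.9%) showed such separation, against 33.3% by chance, and 2539 had an unadjusted p under 0.05. The count rested on single arrays. It was 148 without f/f replicate 2 and 7 without f/f replicate 3, and without d/d replicate 4 or d/d replicate 5 limma called 0 genes, with 1931 and 1583 at an unadjusted p under 0.05. It was also 102 with trend and robust settings and 10 of the genes at or above the median level.

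Of 40 gene lists, 16 passed the camera threshold, 12 higher and 4 lower in the arrays labelled d/d. With an estimated correlation camera passed 0 lists, and the smallest adjusted p was 0.564. That test gave each of the 16 lists the largest adjusted p of all settings tried. Fry passed 1 list as moving one way, the inflammatory cytokines and NF-kB targets (adjusted p = 0.0498), and 21 as changing in either direction.

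**Figure D2:**
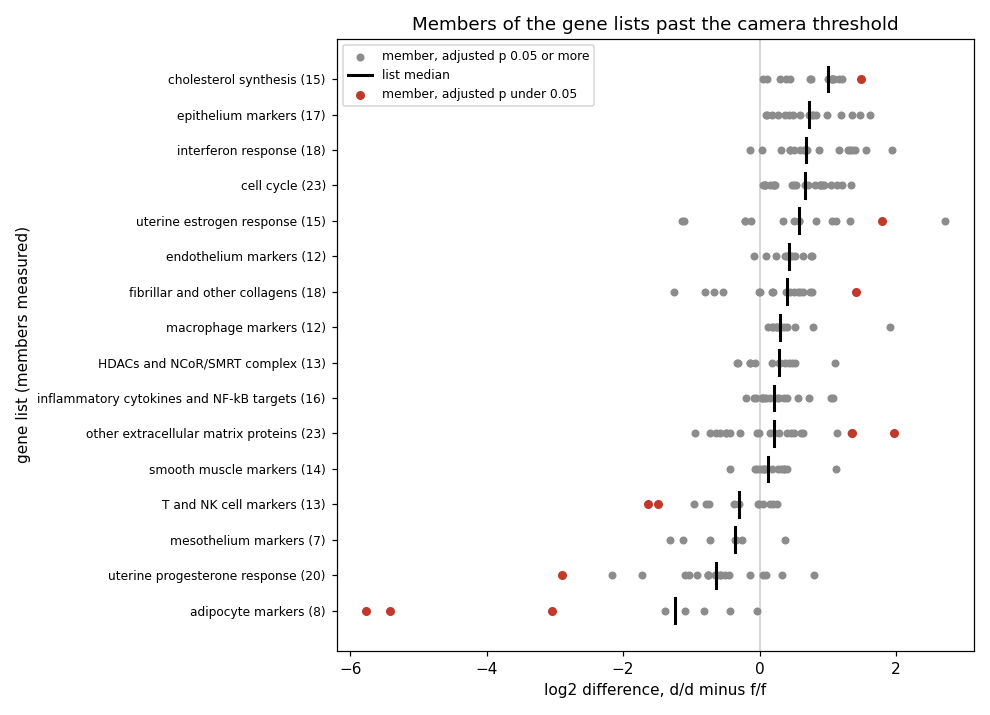
Log2 difference, d/d minus f/f (horizontal axis), of each measured member of the 16 gene lists past the camera threshold (vertical axis, members measured in brackets); points are genes, red where the adjusted p over all genes was under 0.05, and black bars are list medians. Medians run from -1.24 for adipocyte markers to 1.01 for cholesterol synthesis.

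Cholesterol synthesis had the smallest camera p of the lists. All 15 measured members lay above 0, with a median of 1.01 (adjusted p = 7.8e-12 in camera, adjusted p = 0.564 with an estimated correlation). Cyp51 passed over all genes, and adjusted over the list alone 10 members were higher. Msmo1 (1.21, SE 0.20), Fdft1 (squalene synthase, 1.16, SE 0.17) and Sqle (squalene epoxidase, 1.09, SE 0.15) had the next largest differences, none of them past the threshold over all genes. The f/f arrays stood close to each other for this list, with a median difference of 0.02, whereas the arrays labelled d/d differed by 0.36 (replicate 5 minus replicate 4). The list median was 0.69 without d/d replicate 5 and 1.26 without d/d replicate 4. With the mean of all probe sets of a gene, the list median was 0.60.

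The epithelium, interferon and cell cycle lists were also higher. Epithelium markers lay above 0 in 17 of 17 members, with a median of 0.73 (camera adjusted p = 8.9e-09, adjusted p = 0.564 with an estimated correlation). Limma passed 0 of them over all genes, 10 adjusted over the list alone and 10 at an unadjusted p under 0.05. The keratins Krt18 and Krt8 differed by 1.61 (SE 0.24) and 1.36 (SE 0.27). Interferon response genes had a median of 0.68, with 17 of 18 above 0 (camera adjusted p = 8.9e-09, adjusted p = 0.564 with an estimated correlation). Of these, 0 passed over all genes in limma, 8 adjusted over the list alone and 12 at an unadjusted p under 0.05, and the antiviral genes Mx1 and Oas1a differed by 1.95 (SE 0.29) and 1.40 (SE 0.40). All 23 cell cycle genes lay above 0, with a median of 0.66 (camera adjusted p = 2.3e-06, adjusted p = 0.564 with an estimated correlation). None of them passed in limma, 0 over all genes and 0 adjusted over the list alone, with 3 at an unadjusted p under 0.05. The mitotic kinases Aurka and Plk1 differed by 1.35 (SE 0.48) and 1.21 (SE 0.50).

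The f/f arrays stood apart from each other in these 3 lists. In f/f replicate 2 the median member was above f/f replicate 3 by 0.90 for the cell cycle, 0.67 for interferon and 0.60 for epithelium. Without f/f replicate 3 the medians between genotypes were 0.23, 0.56 and 0.49, and without f/f replicate 2 they were 1.12, 0.96 and 0.97, with each list still past the camera threshold.

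Hormone response lists moved in opposite directions. Progesterone response genes fell as a list, with 16 of 20 members below 0 and a median of -0.64 (camera adjusted p = 2.5e-06, adjusted p = 0.564 with an estimated correlation). Fst passed over all genes, and adjusted over the list alone 8 members were lower, including Zbtb16, a transcription factor induced by progestins (-1.73, SE 0.29). Lrp2, with the largest difference after Fst, stood at 2.80 and 5.66 on the f/f arrays and at 2.09 and 2.04 on the arrays labelled d/d. In the progesterone list the f/f arrays differed by a median of -0.17 (replicate 2 minus replicate 3), and its median was -0.52 without f/f replicate 3. Gaps of single members were wider and ran both ways. Among members singled out after their values were seen, Acod1 stood at 3.23 and 5.77 on f/f replicates 2 and 3. Hdc stood there at 6.19 and 8.16, and Errfi1, in the opposite order, at 9.29 and 8.46. Estrogen response genes rose as a list, with 10 of 15 above 0 and a median of 0.57 (camera adjusted p = 0.0189, adjusted p = 0.564 with an estimated correlation, 0.235 in camera without d/d replicate 5). Sprr2f passed over all genes, and adjusted over the list alone 3 members were higher and 1 lower. Ltf (lactoferrin) stood at 10.42 and 8.17 on the f/f arrays and at 12.06 and 11.96 on the arrays labelled d/d, whereas Greb1, a further estrogen receptor target, differed by -1.13 (SE 0.14). The median of this list differed by 0.34 between the f/f arrays and between genotypes by 0.27 without f/f replicate 3 and 0.28 without d/d replicate 5. Steroid receptors and coregulators did not pass (median -0.26, camera adjusted p = 0.0595), with 0 members past the threshold over all genes in limma, 3 lower adjusted over the list alone and 6 at an unadjusted p under 0.05. Pgr, the progesterone receptor, had the largest difference of that list, 10.31 ± 0.03 against 9.57 ± 0.003 (SD, n = 2 each), with an adjusted p of 0.0904.

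**Figure D3:**
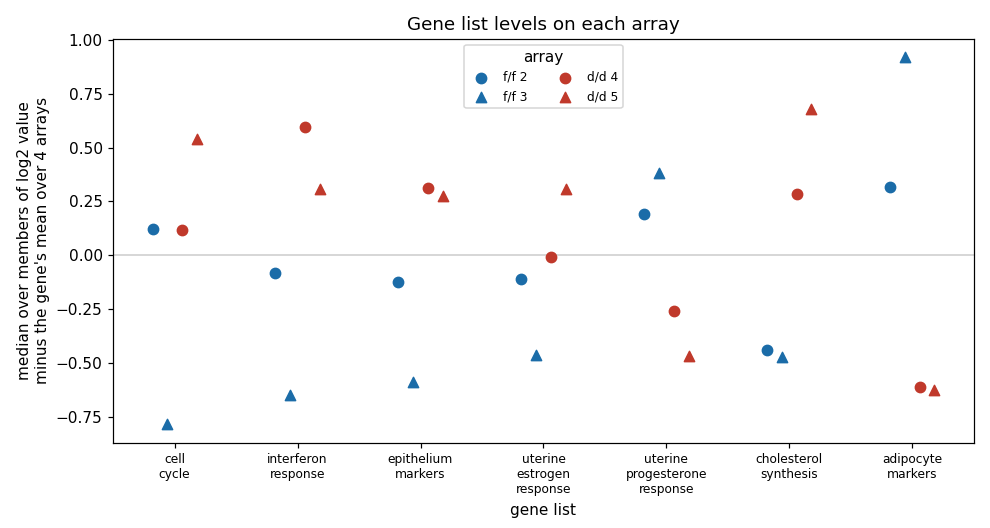
Median over the members of 7 gene lists (horizontal axis) of the log2 value minus the gene's mean over the 4 arrays (vertical axis), one point per array, blue for f/f and red for arrays labelled d/d. For the cell cycle, f/f replicate 2 (0.12) lies with d/d replicate 4 (0.12) and f/f replicate 3 lies lowest (-0.79), while for cholesterol synthesis both f/f arrays lie together (-0.44 and -0.47).

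Extracellular matrix genes were split. Collagens had 13 of 18 members above 0 and a median of 0.40 (camera adjusted p = 0.0025, adjusted p = 0.564 with an estimated correlation). Adjusted over the list alone, 10 were higher and 4 lower, and Col8a1 passed over all genes. Col14a1, a fibril-associated collagen, differed by -1.25 (SE 0.16) and the basement membrane collagen Col15a1 by 0.77 (SE 0.16). Of 23 other matrix proteins, Fbn2 and the proteoglycan Bgn (biglycan, 1.35, SE 0.11) rose, and adjusted over the list alone 8 were higher and 4 lower. The list passed camera narrowly (median 0.21, adjusted p = 0.0440, adjusted p = 0.564 with an estimated correlation), and without f/f replicate 2 (median 0.03, adjusted p = 0.243) or d/d replicate 4 (median 0.09, adjusted p = 0.205) it did not pass. Without f/f replicate 3 its median was 0.39. The elastic fibre genes Mfap4 and Eln differed by 1.35 (SE 0.23) and 1.34 (SE 0.21). Matrix proteases and inhibitors did not pass (median 0.05, camera adjusted p = 0.0652), although Mmp7, matrilysin, differed by 2.95 (SE 0.46, limma adjusted p = 0.109).

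Adipocyte markers fell as a list, with 8 of 8 members below 0 and a median of -1.24 (camera adjusted p = 8.2e-08, adjusted p = 0.564 with an estimated correlation). Fabp4, Adipoq and Retn passed over all genes, and adjusted over the list alone 6 were lower. The list median was -4.23 among genes at or above the median level, where only Fabp4, Adipoq, Retn and Plin4 (-0.81) remained. It was -0.41 with values under 4 set to 4, a setting chosen after the data were seen. The f/f arrays differed here too, by -0.60 (replicate 2 minus replicate 3). Genes listed as markers of mesothelium, the lining of the outer uterine surface, fell as a list (median -0.37, 6 of 7 below 0, camera adjusted p = 0.0063, adjusted p = 0.564 with an estimated correlation). Whether these genes are particular to that lining in a whole uterus was not tested. Limma passed 0 of these over all genes and 2 adjusted over the list alone, Wt1 (-1.12, SE 0.13) and Upk3b (-1.31, SE 0.23), the same number as at an unadjusted p under 0.05. The mesothelium median was -0.22 without f/f replicate 3 and -0.66 without f/f replicate 2. The list no longer passed among genes at or above the median level (median -1.12, camera adjusted p = 0.0951), where only Upk3b, Wt1 and Krt19 remained. With values under 4 set to 4 it did not pass either (median 0.00, camera adjusted p = 0.239).

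Markers of immune and vascular cells moved in different directions. The T and NK cell list had 9 of 13 members below 0 and a median of -0.30 (camera adjusted p = 0.0078, adjusted p = 0.564 with an estimated correlation, 0.103 in camera without d/d replicate 5). Without f/f replicate 2 that median was -0.18, and with the mean of all probe sets of a gene -0.10. With values under 4 set to 4 the median was 0.00 and the list did not pass (camera adjusted p = 0.559). All 4 members above 0 were T cell genes, and the lower ones were mainly genes of NK and cytotoxic cells. Nkg7, a granule membrane protein of cytotoxic lymphocytes, fell by 1.64 (SE 0.14) and Gzmb (granzyme B) by 1.49 (SE 0.12), and adjusted over the list alone 5 members were lower. Macrophage markers rose as a list, with 12 of 12 above 0 and a median of 0.30 (camera adjusted p = 1.9e-04, adjusted p = 0.564 with an estimated correlation). Without f/f replicate 3 that median was 0.11 and the camera adjusted p 0.0695, without f/f replicate 2 the median was 0.53, and the f/f arrays differed by 0.45. Limma passed 0 macrophage members over all genes, 1 adjusted over the list alone, Cd68 (1.91, SE 0.28), and 2 at an unadjusted p under 0.05. Inflammatory cytokines and NF-kB targets had a median of 0.21 (camera adjusted p = 0.0034, adjusted p = 0.564 with an estimated correlation). Of these, 0 passed over all genes in limma, 2 adjusted over the list alone and 5 at an unadjusted p under 0.05, with Ptgs2 (cyclooxygenase-2) differing by 1.08 (SE 0.19). With values under 4 set to 4 the list median was 0.00 and the list did not pass (camera adjusted p = 0.124). Among genes at or above the median level, where only Nfkbiz, Icam1, Nfkbia and Cxcl1 remained, the median was 0.49. Endothelium markers lay above 0 in 11 of 12 members, with a median of 0.43 (camera adjusted p = 2.3e-05, adjusted p = 0.564 with an estimated correlation). None passed over all genes (0 in limma, 5 at an unadjusted p under 0.05), and adjusted over the list alone 2 were higher, the VEGF receptors Kdr (0.77, SE 0.16) and Flt1 (0.75, SE 0.13). The f/f arrays differed by -0.34 in this list, and its median was 0.23 without f/f replicate 2. Smooth muscle markers had a median of 0.13 (camera adjusted p = 0.0266, adjusted p = 0.66 with an estimated correlation), with adjusted p-values of 0.431 without f/f replicate 2 (median 0.03) and 0.108 without d/d replicate 5. Without f/f replicate 3 the median was 0.22. Of its 14 members, limma passed 0 over all genes, 1 adjusted over the list alone, Des (desmin, 1.12, SE 0.16), and 2 at an unadjusted p under 0.05.

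The list of HDACs and the NCoR/SMRT complex holds mostly other HDACs, and Ncor1 and Ncor2, which encode NCoR and SMRT, were not measured. The list had 8 of 13 measured members above 0 and a median of 0.28 (camera adjusted p = 0.0199, adjusted p = 0.564 with an estimated correlation). It did not pass without f/f replicate 3 (median 0.17, camera adjusted p = 0.179) or without d/d replicate 4 (median 0.08, camera adjusted p = 0.112). With the mean of all probe sets of a gene its median was 0.18. Limma passed 0 members over all genes, 2 adjusted over the list alone and 4 at an unadjusted p under 0.05. Tbl1xr1, a subunit of the corepressor complex, stood at 6.97 ± 0.10 against 8.07 ± 0.07 (SD, n = 2 each) with an adjusted p of 0.0523 in limma, and Hdac7 differed by 0.52 (SE 0.11).

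The other 24 lists did not pass camera. Over all their members limma passed 1 higher (Cdkn1a) and 1 lower (Tppp3) over all genes, and adjusted over the list alone 14 were higher and 15 lower, spread over 12 lists. Implantation and decidualization genes had a median of 0.08 (adjusted p = 0.154), with Lif, the cytokine required for implantation, at 3.89 ± 0.07 against 5.11 ± 0.57 (SD, n = 2 each) and a limma adjusted p of 0.176. Wnt and Hox genes of the Mullerian duct had a median of -0.12 (adjusted p = 0.153), and Hoxa11 and Hoxa10, which pattern the uterus, differed by -1.03 (SE 0.11) and -0.92 (SE 0.18). Stroma markers had a median of -0.11 (adjusted p = 0.131) and uterine gland markers of -0.29 (adjusted p = 0.474). Hedgehog signalling (-0.24), mast cell (-0.23), fatty acid synthesis (0.17), B and plasma cell (0.20), immediate early (0.09) and p53 target (0.06) lists had adjusted p-values from 0.0587 to 0.474. PPAR targets (-0.08), circadian clock (-0.02), TGF-beta and YAP targets (-0.003), neutrophil (0.02), eosinophil (0.04), erythroid (-0.03), Schwann cell (-0.003) and skeletal muscle (-0.05) lists had medians near 0, with adjusted p-values from 0.304 to 0.89. For the TGF-beta and YAP, Schwann cell and ovary lists, camera's direction was higher although the median was below 0. Ovary and steroidogenic (-0.02), oviduct and ciliated cell (-0.12) and vagina and cervix squamous (0.04) lists, which mark neighbouring tissue, did not pass either (adjusted p-values from 0.304 to 0.883). Tppp3, of the oviduct and ciliated cell list, fell by 1.21 (SE 0.10). Ovgp1, with the largest difference of that list (-1.92, SE 1.58, limma adjusted p = 0.662), was high on 1 array only. It stood at 2.48 and 7.56 on f/f replicates 2 and 3, and at 3.11 and 3.08 on the arrays labelled d/d. What raised it in f/f replicate 3 was not tested. In the same list Ccdc39 (means 2.45 and 2.23) and, singled out after its values were seen, Foxj1 (2.44 and 2.40) lay at the floor in both genotypes. Y-linked genes lay at the floor of the arrays and had a median of -0.08 (adjusted p = 0.637).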

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

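Setting log2 values under 4 to 4 was chosen only after the result was seen. No paired analysis was possible because the genotypes share no replicate numbers. All 47 genes kept their direction in every gene-level setting that tested them. Of the 20 with several probe sets, 4 had another probe set of opposite sign, Col8a1 of the named genes among them. The count of genes past the threshold moved with the setting. It was 102 (40 higher, 62 lower) with trend and robust settings, 68 (27 higher) after a further quantile normalization, 10 (3 higher, 7 lower) among genes at or above the median level, and 8 (1 higher, 7 lower) with values under 4 set to 4. Of the 47, the calls shared were 47, 47, 10 of 28 tested, and 1. Without a p, 1055 genes (529 higher, 526 lower) differed at least 1.5-fold with no overlap, and chance gives no overlap for 33.3% of genes. Leaving out 1 array gave 0 to 148 genes (0 to 91 higher, 0 to 57 lower), where the lone array is assumed to vary like the other genotype. Median centring (50), the mean of all probe sets (51) and the probe set level (43) stayed within 1.5 times. Settings without an array hold fewer samples and the brighter-gene setting fewer genes, and otherwise the cause was not tested. Lists past the threshold numbered 15 to 19 under the other settings, 0 in camera with an estimated correlation and 1 by fry. With values under 4 set to 4, the T and NK cell, inflammatory and mesothelium lists lost their call. Hdac3 differed by 0.27 to 0.41 under every setting and never passed. No detection calls came with the arrays, so signal over background could not be set for the dim genes.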

Other observations

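The tests of hormonal phase, epithelium share, leukocyte share and other groupings of the arrays were chosen only after the result was seen, whereas the further adipocyte and NK cell lists were written before their values were seen. The genes of the next paragraph were singled out after their values were seen.

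Meg3 and Rian, long noncoding RNAs of one imprinted, maternally expressed cluster that lie close together in the GRCm38.p6 gene table, fell together in the arrays labelled d/d, by 1.87 (SE 0.18) and 1.95 (SE 0.16) on the log2 scale (limma adjusted p = 0.0477 and 0.0381). The brighter Meg3 probe sets moved alike, and the dimmest of both genes did not. Mirg, from the same cluster, lay at the floor of all 4 arrays (means 2.37 and 2.33). Both retinoic acid binding proteins were low in the arrays labelled d/d, with Crabp1 at 6.44 against 3.43 (adjusted p = 0.0523) beside the fall of Crabp2. In the family of interferon-inducible genes around Mndal, Ifi202b stood at 4.12 and 2.70 on the f/f arrays and at 5.72 and 5.39 on the arrays labelled d/d (adjusted p = 0.171), opposite to Mndal. Naip5, a sensor of bacterial flagellin with close relatives in the genome, fell by 1.97 (SE 0.14). All 4 arrays have just 3 splits into pairs, too few for a share under 0.05. The real split gave 47 genes against at most 0 for the other splits (348 and 366 genes at an unadjusted p under 0.05, against 2539), so 1 of 3 splits gave as many. Each pair of the other splits mixes the genotypes, so any difference between genotypes widens the spread within pairs and lowers these counts. The contrast of 47 with 0 therefore decides nothing.

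Adipocyte transcripts were the deepest loss in the arrays labelled d/d, and Car3, a carbonic anhydrase abundant in fat and singled out after its value was seen, went with them at 10.06 and 10.48 against 2.98 and 5.52 (adjusted p = 0.0842). A candidate explanation is fat attached to the f/f uteri and largely absent from the others. A further list of adipocyte transcripts had a median of -0.11 over 20 measured members, 14 of them below 0. It lay at percentile 4.49 of 10000 random lists of matched level, whose genes were drawn independently of each other. Limma passed 0 of the 20 over all genes, with 5 at an unadjusted p under 0.05. Several of those members are also expressed by the uterus itself (Lpl, singled out after its values were seen, ranged from 8.79 to 9.52 over the arrays), so fat and a loss of these transcripts within uterine tissue cannot be told apart. Hormonal phase was tested by where f/f replicate 2 lies between f/f replicate 3 (0) and the arrays labelled d/d (1). Over the 5 members of the fixed adipocyte list lower by 1 or more, the median position was 0.16, with 1 member as far as 0.52. These members were picked by the size of their fall, which favours a position near 0, so this value decides nothing. A contribution of phase stays open, as does a genotype effect.

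Higher cell cycle, interferon and epithelium transcripts in the arrays labelled d/d went with a gap between the f/f arrays. Over the 58 members of these lists, f/f replicate 2 exceeded f/f replicate 3 by a median of 0.67, in 52 members. These lists were fixed before the data were examined but pooled after this gap had been seen, so it describes the arrays and does not test what separates them. Estrous stage is not given in the sources used here, and whether a difference in cycle stage contributes was left open. Against f/f replicate 2 alone, the median difference of the arrays labelled d/d was 0.35, compared with 0.68 against both. A larger share of epithelium is also open, since after removing the common shift of the epithelium list limma found 1 of 17 members to depart (Krt18), with little power at 2 arrays per genotype, and a genotype effect stays open beside both.

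Lower NK cell transcripts in the arrays labelled d/d took in 4 genes past the threshold, Nkg7, Gzmb and, singled out after their values were seen, the NK receptors Klra8 (-1.95, SE 0.12) and Klra7 (-1.68, SE 0.16), whose probe sets may read each other's transcripts. The macrophage list did not fall with them, with a median of 0.30 and 12 of 12 members above 0, but that median was 0.11 without f/f replicate 3. This test was chosen after the result was seen and covers macrophages only. Mast cell markers lay below 0 in 8 of 9 members, although that list did not pass (camera adjusted p = 0.0587). Medians of the B and plasma cell (0.20), neutrophil (0.02) and eosinophil (0.04) lists lay above 0, with most neutrophil and eosinophil members near the floor. A smaller share of some other leukocytes therefore stays open. Hormonal phase stays open. The median position of f/f replicate 2 between f/f replicate 3 and the arrays labelled d/d was 0.014 over these 4 genes, but they were picked because they passed limma, which favours genes whose f/f arrays lie close together relative to the difference, so this value decides nothing. A further list of 15 NK cell transcripts had a median of -0.40, with 13 below 0, although limma passed 0 of them singly (10 at an unadjusted p under 0.05). None of 10000 random lists of matched level was as low. Genes of the random lists were drawn independently, whereas transcripts of a single cell type may move together. That rank therefore does not measure the spread between samples. Fewer NK cells, or less of their RNA, in the uteri labelled d/d remains a hypothesis beside hormonal phase. The largest differences of the further list were those of Klrd1 (5.62 against 4.51) and Eomes (3.79 against 2.71). Its median member, Tbx21, lay near or below the lower quartile of all genes (2.45). It stood at 2.32 and 2.50 on the f/f arrays and at 1.90 and 2.12 on the arrays labelled d/d. Klrc1, Gzmc and Txk, also below 0, lay at the floor on all 4 arrays. The list's median and some of its falls therefore depend on background.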
